A study of Homo sapiens with 6 samples.

How the data were processed

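RNA was measured by sequencing in 6 libraries of MCF7, an established breast cancer cell line that expresses the estrogen receptor. Per the labels' protocols, the cells were grown in EMEM with 5% fetal bovine serum and transfected transiently, with the Xfect reagent, with a vector carrying the open reading frame of IKKe or, for the controls, of LacZ. RNA was isolated with Trizol, and libraries were made with Illumina's stranded TruSeq kit for total RNA and sequenced as paired reads of 76 nt, per the labels' protocols. The labels give 3 control and 3 IKKe libraries. The control column whose name ended in an additional letter was matched to the control sample carrying that number in its title. It is control library 1, and the meaning of the letter is not given in the sources used here.

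Per the submitters' processing notes, Trimmomatic 0.33, STAR 2.4.2 and RSEM 1.2.29 were used with the GRCh38 build. The column names of the deposited table also name STAR and RSEM gene results. The annotation release, the strand setting of the counting and the method behind the size factors are not given in the sources used here. The deposited table held a normalised signal for 60725 genes, which the authors had scaled and which is scaled neither to a fixed total nor to gene length. Within each library the deposited values were multiples, to 2 decimals, of a single step, as RSEM expected counts divided by a size factor would be. Between 80.3% and 84.4% of the nonzero values were whole multiples of the step within 0.01, so the values were not treated as whole reads and no test for whole reads was run. They are called normalised expected counts here. Because RSEM shares reads between similar genes, values of near-identical genes are estimates of a split, and 86 of the tested genes had values identical to those of another gene.

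Division by the step gave the depth of each library in expected counts, which is the total behind its values. The totals were 16.7 M, 35.6 M and 17.5 M in control libraries 1, 2 and 3, and 33.8 M, 28.3 M and 23.2 M in IKKe libraries 1, 2 and 3. The deposited totals after scaling lay between 23.0 M and 25.7 M. Counting error covers only part of the error of a value, since reads without molecular identifiers are not independent molecules.

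The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2 of the normalised expected count plus a pseudocount of 1, over the 16154 genes whose mean over the 6 libraries was at least 10. The test was two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. Fold changes are on this log2 scale, which understates the change of low genes, and errors of log2 fold changes are standard errors (SE) while errors of group means are standard deviations (SD). Intervals are 95% confidence intervals from the same model. The model had no covariates, since the labels name no batch, day or pairing. The p of IKBKE was also taken from an exact two-sided permutation test.

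The 30 gene lists were fixed before the data were examined, as were the test, its samples, the rule for named genes and most of the alternatives. Lists were tested with limma's camera, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 30 lists, and again with a correlation estimated from the data, with camera on ranks and with fry. Autophagy and lysosome genes had an estimated correlation of -0.031, below the preset 0.01. Their unadjusted camera p still rose, from 1.09e-05 to 0.00816, and that of IL6 signalling (-0.011) from 0.00096 to 0.0233. A call lost with an estimated correlation therefore need not reflect correlation between genes. For lists with an estimate above 0.01, the part due to correlation was not separated. For each list the number of members past the threshold is given over all genes tested and adjusted over the list alone. The lists covered interferons with chemokines of the IRF3 pathway, interferon-stimulated genes, MHC class I presentation, NF-kappaB targets, the kinase complexes of IKKe, nucleic acid sensing and IL6 signalling. Further lists covered estrogen receptor targets, luminal identity, mitosis, DNA replication, replication histones, p53 targets, apoptosis regulators, the unfolded protein response, ATF4 targets, heat shock proteins, immediate early genes, epithelial-mesenchymal transition, cholesterol synthesis, glycolysis with hypoxia, oxidative phosphorylation, and autophagy with lysosomes. Mitochondrially encoded genes, structural small RNAs and ribosomal proteins stood for RNA composition, and markers of fibroblasts, leukocytes, basal epithelium and endothelium for other cell types. IKBKE was in no list.

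The named genes were IKBKE, the 15 genes with the largest rise and the 15 with the largest fall among called genes with a symbol, a mean of at least 50 and groups that did not overlap, and up to 4 called members with the smallest p per list. Where fewer than 5 genes passed in a direction, the 5 with the smallest p were named. From a list with no called member, up to 2 members with the highest mean were named. TBK1, IKBKB, CHUK, IKBKG and ESR1 were named whatever their p. Coordinates, transcript length and GC content come from GENCODE 29 on GRCh38, matched by gene identifier without its version. Of the 60725 identifiers 57055 matched, and 16014 of the tested genes (99.1%) had a length and GC content.

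The test was tried on simulated data for 16154 genes with the means of the real libraries. With the spread of each group as measured, it called 41 of 100 genes changed by 2-fold and 88 of 100 changed by 4-fold, along with 24 unchanged genes. With a spread that was equal in both groups, it called 38 and 88 of 100, and 7 unchanged genes. With the spread as measured, unchanged genes were a larger share of the calls than the 0.05 that the adjustment aims at. Adjusted p-values of called genes may therefore be too small.

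The alternatives were another pseudocount (0.5 or 5), no filter or a mean of at least 50, and scaling to equal upper quartiles, equal totals, median of ratios or equal quantiles. Others were a fit without trend, a robust prior, library weights, protein-coding genes only, leaving out each library, a fold change of at least 1.5 and an adjusted p under 0.1. Chosen after the data were seen were limma voom with and without library quality weights on the recovered expected counts (voom alone means the fit without them), and a correction by splines of 5 degrees of freedom on GC content and log2 transcript length per library. Thinning the recovered counts to the smallest total followed by median-of-ratios scaling, leaving out control libraries 1 and 3, and the spline or the thinning without control library 2 were chosen after the data were seen as well. Similarity of libraries was described by principal components of the log2 values and, for each pair, by the median chi-square of the recovered counts over the genes with at least 20 counts in the pair, relative to the median that sampling noise gives. No library was left out of the main test.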

Results

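Total RNA from MCF7 cells, a line derived from a luminal breast cancer, was sequenced after transient transfection with a vector for the kinase IKKe (3 libraries) or for LacZ (3 control libraries). IKKe, encoded by IKBKE, is a kinase related to TBK1 that acts in the activation of interferon genes. The depth was 16.7 M, 35.6 M and 17.5 M expected counts in control libraries 1, 2 and 3, and 33.8 M, 28.3 M and 23.2 M in IKKe libraries 1, 2 and 3. All values below are expected counts scaled by the authors with a single factor per library. The comparison of IKKe with control libraries asks which transcripts differ when IKKe is overexpressed.

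IKBKE itself (ENSG00000263528.7, chromosome 1, 206470476 to 206496889, plus strand, GRCh38) was far higher in the IKKe libraries. Its normalised expected count was 294, 436 and 559 in control libraries 1, 2 and 3, and 44708, 44794 and 50165 in IKKe libraries 1, 2 and 3, where it made up 0.185% of the total. The group means were 429.7 ± 132 and 46556 ± 3126 (SD, n = 3 each), and the rise was 112-fold, with a 95% interval of 77.8 to 160 (log2 6.80 ± 0.23 SE, limma adjusted p = 2.66e-05). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. The labels give a 200-fold increase by quantitative PCR at 48 h after transfection, above the upper bound of 160 from sequencing. The values do not separate transcripts of the vector from those of the cell's own gene, and an exon of C1orf147 overlaps IKBKE on the other strand.

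With IKKe, the genes of interferon beta and of the type III interferons rose, together with the chemokine gene CCL5. IFNB1 (ENSG00000171855.6, chromosome 9, 21077105 to 21077963, minus strand), which encodes interferon beta, rose from 51.0 ± 16.6 to 687 ± 16.8 (log2 3.77 ± 0.24 SE, adjusted p = 0.000551). The 3 interferon lambda genes lie side by side on chromosome 19, with IFNL3 at 39243553 to 39245129, IFNL2 at 39268514 to 39270092 and IFNL1 at 39296325 to 39298673. IFNL1 (ENSG00000182393.2) rose from 87.0 ± 12.7 to 1555 ± 50.4 (log2 4.15 ± 0.15), IFNL2 (ENSG00000183709.7) from 26.3 ± 3.18 to 632 ± 4.91 (log2 4.54 ± 0.17), and IFNL3 (ENSG00000197110.8) from 36.3 ± 13.1 to 687 ± 46.5 (log2 4.26 ± 0.25). IFNL2 and IFNL3 are near-identical, so the split of reads between them is uncertain. CCL5 (ENSG00000271503.5, chromosome 17, 35871491 to 35880793, minus strand), a chemokine that attracts T cells, rose from 160.8 ± 31.9 to 1232 ± 142 (log2 2.94 ± 0.18, adjusted p = 0.000518). These genes belong to a list of interferons and IRF3 chemokines, of which 8 of 12 members could be tested. Of these, 6 rose over all genes tested and 7 adjusted over the list alone (camera adjusted p = 6.88e-16). It was also the only list past the threshold with an estimated correlation (adjusted p = 0.0293). The other members were chosen after their values were seen. TNFSF10, which encodes the death ligand TRAIL, rose from 135 ± 44.4 to 505 ± 6.35 (log2 1.95 ± 0.26). CXCL11 had a log2 fold change of 2.07 (adjusted p = 0.0559), and CXCL10 one of 0.45 with 180, 269 and 925 in control libraries 1, 2 and 3.

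**Figure D1:**
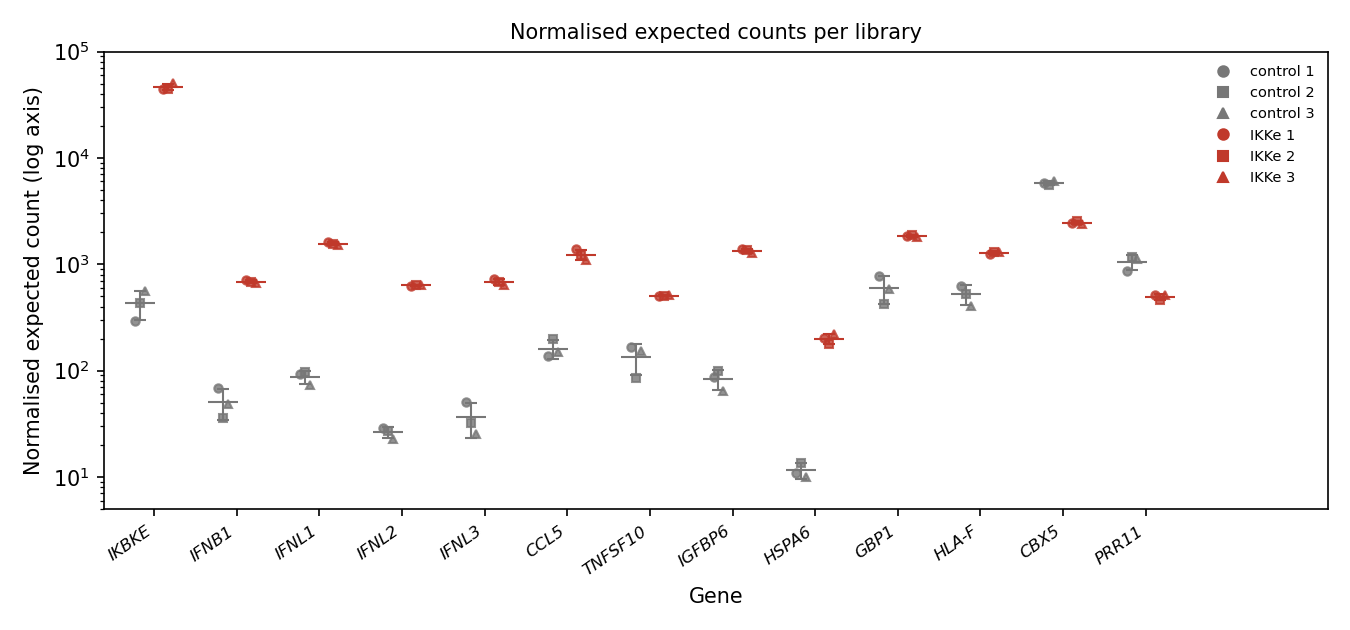
Normalised expected count (log axis) of 13 genes in each library, with the control libraries in grey and the IKKe libraries in red; symbols mark the replicate, horizontal dashes the group mean and error bars the SD (n = 3 per group). Each plotted gene lies higher in all IKKe libraries than in any control library, except CBX5 and PRR11, which lie lower.

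Genes induced by interferon and genes of antigen presentation were higher as groups, with few single genes past the threshold in the main test. Of 57 tested interferon-stimulated genes, 2 rose over all genes tested, while 35 rose and 1 fell adjusted over the list alone. GBP1, a guanylate-binding protein, rose from 598 ± 178 to 1856 ± 35.5 (log2 1.67 ± 0.21), and LAMP3, a lysosomal membrane protein, from 355 ± 19.2 to 667 ± 29.4 (log2 0.91 ± 0.13). The median log2 fold change of the list was 0.72 (camera adjusted p = 6.88e-16), a call that was lost with an estimated correlation (adjusted p = 0.199). Control library 1 lay above the mean of the other controls on this list by a median of 0.43 on the log2 scale. Without control library 1, 26 of the 57 rose, without control library 2, 21, and without control library 3, 4. With any 1 of the IKKe libraries left out, 0 rose. Of 17 tested genes of MHC class I presentation, 2 rose, and 16 rose adjusted over the list alone. These were HLA-F, a non-classical class I gene (log2 1.33 ± 0.17), and PSMB10, a subunit of the immunoproteasome (log2 1.34 ± 0.16). The median of the MHC list was 0.96 (camera adjusted p = 5.62e-14, adjusted p = 0.182 with an estimated correlation), and control library 1 lay 0.55 above the other controls on it. Without control library 1, 12 of the 17 rose, without control library 2, 9, and without control library 3, 1. With any 1 of the IKKe libraries left out, 0 rose. HLA-F is overlapped by 3 genes on the other strand, and PSMB10 by AC040162.1 on the same strand.

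None of 34 tested NF-kappaB targets passed over all genes with limma or voom (1 rose with limma after quantile scaling), and 9 rose adjusted over the list alone. At an unadjusted p under 0.05, 15 were higher and 0 lower. NFKBIA, the inhibitor that NF-kappaB induces, had means of 2578 ± 363 and 4086 ± 98.1 (log2 0.67 ± 0.14, adjusted p = 0.116), and NFKBIZ 1832 ± 953 and 3110 ± 70.3 (log2 0.88 ± 0.30, adjusted p = 0.23). The list's median was 0.51 (camera adjusted p = 4.35e-07, adjusted p = 0.14 with an estimated correlation). The kinases related to IKKe and the non-kinase subunit IKBKG did not pass. TBK1 had a log2 fold change of 0.03 ± 0.17 (adjusted p = 0.943), IKBKB 0.09 ± 0.15 (0.772), CHUK -0.03 ± 0.15 (0.93) and IKBKG 0.33 ± 0.15 (0.292), where IKBKG shares an exon region with G6PD on the other strand. Among 16 tested members of the IKK and TBK1 complexes 0 passed over all genes with limma or voom (1 rose with voom's quality weights), 1 rose adjusted over the list alone, and 1 was higher and 1 lower at an unadjusted p under 0.05 (camera adjusted p = 0.186). The adapter MAVS, its most abundant member, had a log2 fold change of -0.33 ± 0.12 (adjusted p = 0.237). Among 12 tested nucleic acid sensors 0 passed with limma or voom, 4 rose and 2 fell adjusted over the list alone, and 4 were higher and 2 lower at an unadjusted p under 0.05. EIF2AK2, the kinase PKR, was the most abundant of them (log2 -0.48 ± 0.16, adjusted p = 0.224), followed by DDX58, the sensor RIG-I (log2 0.23 ± 0.17, adjusted p = 0.486). Their median was 0.30 (camera adjusted p = 0.0316, adjusted p = 0.229 with an estimated correlation), and the call was also lost without control library 2 (adjusted p = 0.205), without control library 3 (0.0692), with a mean of at least 50 (0.0717) and with camera on ranks (0.0534). Control library 1 lay at 0.21 above the control mean on this list, against 0.31 to 0.38 in the IKKe libraries.

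**Figure D2:**
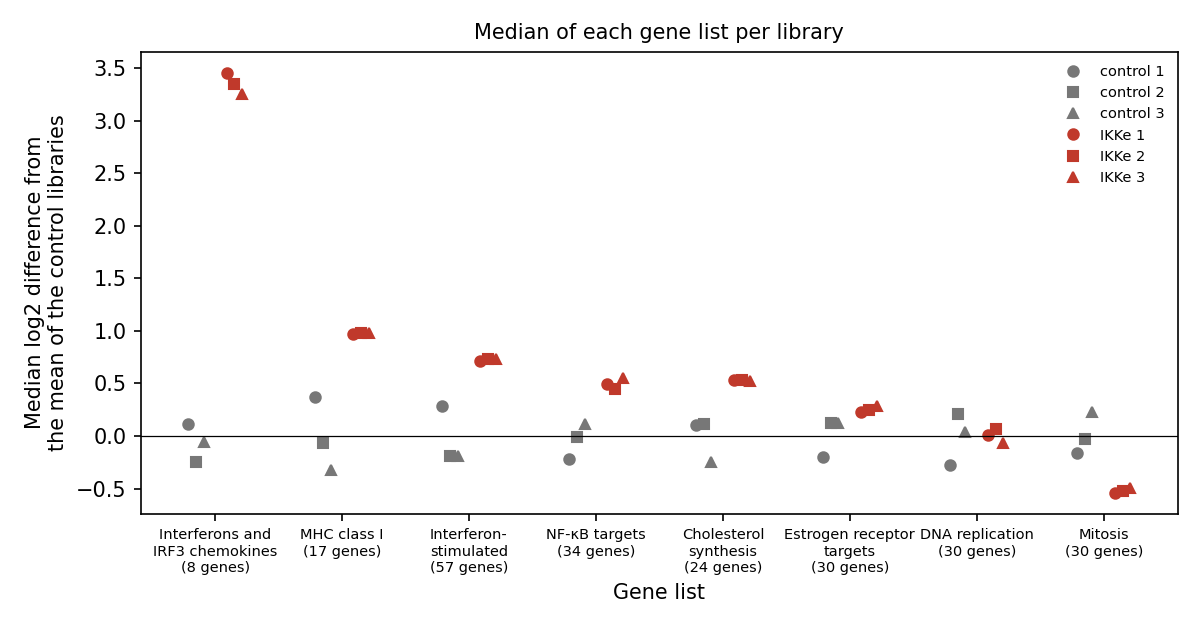
Median over the members of 8 gene lists of the log2 difference from the mean of the 3 control libraries, for each library (control grey, IKKe red; symbols mark the replicate); the number of tested genes stands under each list. The IKKe libraries lie between 3.26 and 3.46 for interferons and IRF3 chemokines and between -0.54 and -0.49 for mitosis, while the control libraries spread from -0.19 to 0.29 for interferon-stimulated genes.

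In all, 46 genes rose and 4 fell, of which 44 and 3 are annotated as protein coding, and 42 rose by at least 2-fold. In the simulation with the measured spread 24 unchanged genes were called, so some of these calls may be false. Apart from IKBKE and outside the interferon lists, the largest rises were those of IGFBP6 and HSPA6. IGFBP6 (ENSG00000167779.7, chromosome 12, 53097436 to 53102345, plus strand), which binds insulin-like growth factors, rose from 83.5 ± 18.1 to 1336 ± 57.2 (log2 4.01 ± 0.19, adjusted p = 0.000108). HSPA6 (ENSG00000173110.7, chromosome 1, 161524540 to 161526910, plus strand), a stress-inducible HSP70 protein, rose from 11.5 ± 1.90 to 199 ± 21.7 (adjusted p = 0.000377). HSPA7 is a close copy of HSPA6, and how reads were split between them was not examined. RAET1L, a ligand of the NKG2D receptor of natural killer cells, rose by 3.43 ± 0.24 on the log2 scale, and S100A8, a calcium-binding protein of inflammation, by 2.73 ± 0.33. The rises of the long non-coding RNA RP11-757G1.6 (2.48 ± 0.28), the chemokine receptor gene CXCR4 (2.21 ± 0.30), the urokinase receptor gene PLAUR (2.13 ± 0.30) and RARRES3 (2.11 ± 0.18) were smaller. The keratin genes KRT16 (log2 2.11 ± 0.26, adjusted p = 0.0238) and KRT17 (log2 1.74 ± 0.26, adjusted p = 0.0491) rose as well, and their pseudogene copies make the split of their reads uncertain. They were the 2 risers among 11 tested basal epithelial markers, of which 2 also rose adjusted over the list alone. That list's median was -0.04 and its mean 0.28, and it did not pass as a whole (camera adjusted p = 0.438).

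Among stress genes, 2 of 26 ATF4 targets rose, and 6 adjusted over the list alone. PPP1R15A (GADD34), a phosphatase subunit that reverses the phosphorylation of eIF2-alpha, rose from 634 ± 20.2 to 2181 ± 46.7 (log2 1.78 ± 0.11, adjusted p = 0.000559), and the transcription factor ATF3 rose by 1.27 ± 0.16 on the log2 scale. The list's median was 0.24 (camera adjusted p = 0.000138, adjusted p = 0.182 with an estimated correlation). Control library 1 stood nearly as high on this list as the IKKe libraries, at a median of 0.21 above the control mean against 0.23 in each IKKe library. ATF3 and KLF4 (log2 1.29 ± 0.13) were the 2 risers of 20 immediate early genes, with 6 adjusted over the list alone (camera adjusted p = 0.00507, adjusted p = 0.565 with an estimated correlation, and 0.107 without control library 3). Control library 1 lay at 0.31 above the control mean on this list, within the IKKe range of 0.28 to 0.37. PMAIP1 (NOXA), a pro-apoptotic BCL2-family protein, rose by 1.28 ± 0.17 and was the only riser among 28 apoptosis regulators and 24 p53 targets. Adjusted over the list alone, 3 of the former and 2 of the latter rose. Camera gave adjusted p = 0.00669 for apoptosis regulators (adjusted p = 0.174 with an estimated correlation, and 0.129 without control library 2) and 0.0668 for p53 targets. The small heat shock protein gene HSPB8 (log2 1.27 ± 0.14) was the only riser of the 18 tested members of the heat shock list, which does not hold HSPA6, with 4 adjusted over the list alone. The median of the heat shock list was -0.03 and its mean 0.19 (camera adjusted p = 0.392). Of 30 estrogen receptor targets, HSPB8 and the scaffold gene PDZK1 (302 ± 51.1 to 852 ± 19.4, 2.84-fold) rose, and 4 adjusted over the list alone (median 0.24, camera adjusted p = 0.00507, adjusted p = 0.357 with an estimated correlation, and 0.359 with the preset correlation when control library 1 was left out). ESR1, the estrogen receptor gene, did not pass, with 5736 ± 2189 and 4719 ± 66.4 (log2 -0.19 ± 0.29, adjusted p = 0.732). PLAUR was the only riser among 12 genes of epithelial-mesenchymal transition, with 3 adjusted over the list alone (camera adjusted p = 0.1). On that list control library 1 lay at 0.39 above the control mean and the IKKe libraries between -0.05 and 0.50.

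Only 4 genes fell. CBX5 (ENSG00000094916.13, chromosome 12, 54230940 to 54280133, minus strand), which encodes heterochromatin protein HP1-alpha, had means of 5811 ± 281 and 2462 ± 79.5 and fell by 1.24 ± 0.12 on the log2 scale (adjusted p = 0.00639). Across 23 alternatives its log2 fold change ran from -1.30 to -0.86, and it passed in 20. Its longest transcript is long (11528 nt, GC content 41.8%). Longer genes stood higher in control libraries 1 and 3 (correlation with log2 length 0.35 and 0.15). They stood lower in control library 2 (-0.17) and the IKKe libraries (-0.24 to -0.31), so length bias may add to the fall. PRR11 (ENSG00000068489.12, chromosome 17, 59155499 to 59204705, plus strand), a gene of cell cycle progression, had means of 1049 ± 170 and 496 ± 31.4 and fell by 1.07 ± 0.16 (adjusted p = 0.0491). PRR11 shares exon sequence with AC099850.2 on its own strand and AC099850.3 on the other. The remaining 2 transcripts fell furthest. The long non-coding RNA CH507-338C24.1 (chromosome 21, 7669397 to 7681742, minus strand) had means of 217 ± 71.7 and 3.37 ± 1.59 (log2 -5.64 ± 0.38). CTD-3074O7.11 (chromosome 11, 66509079 to 66533613, plus strand) had 21.9, 26.3 and 24.7 in control libraries 1, 2 and 3 and was listed at 0 in every IKKe library. Against a floor of 3 counts per library, it was at least 8.93-fold lower, a bound that holds only if its reads were assigned correctly. Its exons overlap those of BBS1, DPP3 and ZDHHC24, so its reads cannot be assigned with certainty. LPP had the next smallest p among lower genes (log2 -1.15 ± 0.18) and did not pass (adjusted p = 0.0553). After correction for GC content and length its log2 fold change was -0.64 (limma adjusted p = 0.0309).

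Mitotic genes were lower as a group. All 30 had a negative log2 fold change, with a median of -0.54, and 0 passed over all genes with limma, while 1 did with voom, 7 with voom's quality weights and 7 with library weights in limma. At an unadjusted p under 0.05, 17 were lower and 0 higher, and 15 fell adjusted over the list alone (camera adjusted p = 6.88e-16, adjusted p = 0.161 with an estimated correlation). The most abundant were MKI67, the proliferation marker, with 8723 ± 3478 and 3923 ± 30.8 (log2 -1.08 ± 0.25, adjusted p = 0.135), and ASPM, a spindle protein, with 4885 ± 999 and 2275 ± 31.1 (log2 -1.08 ± 0.17, adjusted p = 0.0565). Genes of DNA replication did not pass as a list in the main test. Their median was 0.01 and their mean -0.04, with MCM4 at -0.01 ± 0.16 and PCNA at 0.01 ± 0.21, and the median turned negative under each of the 4 other scalings, reaching -0.06. Of the 30 replication genes 0 passed with limma or voom, over all genes or adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05 (camera adjusted p = 0.251). The list passed as lower in 3 of 26 alternatives, among them the fit without control library 1 (adjusted p = 0.00114). Replication histones, with 26 tested, did not pass (camera adjusted p = 0.692); HIST2H4A and HIST2H2BE had log2 fold changes of 0.15 ± 0.19 and 0.09 ± 0.18. None of them passed with limma or voom, over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05.

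Lists of metabolism, autophagy, IL6 signalling and luminal identity were also higher as a whole, with 0 members past the threshold over all genes with limma or with voom without quality weights. With quality weights, voom called 2 genes of cholesterol synthesis and 2 of autophagy and lysosomes higher. All 24 genes of cholesterol synthesis had a positive log2 fold change, with a median of 0.53. Of these, 6 rose adjusted over the list alone and 16 were higher at an unadjusted p under 0.05 (camera adjusted p = 6.57e-09, adjusted p = 0.14 with an estimated correlation). SQLE and INSIG1 had log2 fold changes of 0.36 ± 0.13 and 0.58 ± 0.12. Of 24 autophagy and lysosome genes 2 rose adjusted over the list alone and 10 were higher at an unadjusted p under 0.05 (median 0.25, camera adjusted p = 4.07e-05, adjusted p = 0.122 with an estimated correlation), with SQSTM1 at 0.37 ± 0.12 and CTSD with means of 3916 ± 1269.9 and 7793 ± 251 (adjusted p = 0.125). Of 25 glycolysis and hypoxia genes 4 rose adjusted over the list alone and 10 were higher at an unadjusted p under 0.05 (median 0.35, camera adjusted p = 8.58e-05, adjusted p = 0.161 with an estimated correlation), with GAPDH at 0.33 ± 0.18 and PKM at 0.28 ± 0.17. Of 18 genes of IL6 signalling 4 rose adjusted over the list alone, and 5 were higher and 1 lower at an unadjusted p under 0.05 (median 0.41, camera adjusted p = 0.00262, adjusted p = 0.14 with an estimated correlation). JAK1 and JUNB stood at -0.17 ± 0.23 and 0.70 ± 0.16. Among 16 luminal genes 0 rose adjusted over the list alone and 1 was higher at an unadjusted p under 0.05, and the call was lost with an estimated correlation (median 0.24, camera adjusted p = 0.0314, then adjusted p = 0.387). The call was also lost without control library 3 (adjusted p = 0.107). Control library 2 lay at 0.20 above the control mean on this list, close to the IKKe libraries at 0.23 to 0.26, and control library 1 at -0.23. KRT8 and KRT18 stood at 0.81 ± 0.38 and 0.62 ± 0.36. The unfolded protein response (21 genes, camera adjusted p = 0.0759), with XBP1 at 0.45 ± 0.25 and CANX at -0.16 ± 0.16, and nuclear genes of oxidative phosphorylation (34 genes, 0.194), with ATP5B at 0.07 ± 0.13, did not pass. The former passed as higher in 6 of 26 alternatives, among them the fit without control library 1 (adjusted p = 3.07e-05), and control library 1 lay at 0.36 above the control mean against 0.22 to 0.24 in the IKKe libraries. In these lists 0 members passed with limma or voom, over all genes or adjusted over the list alone, and at an unadjusted p under 0.05 3 and 0 were higher and 0 lower.

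RNA composition and the control libraries varied. Mitochondrial transcripts took 18.8% to 21.4% of the total in controls and 17.7% to 18.6% with IKKe, and their 15 genes had a median of -0.20 and did not pass (camera adjusted p = 0.0754). The list passed as lower in 7 of 26 alternatives, among them those without control library 3 (adjusted p = 1.35e-05) and without IKKe library 1 (0.0257). Of these genes 0 passed over all genes with limma or voom (1 fell with voom's quality weights), 1 fell adjusted over the list alone, and 2 were lower at an unadjusted p under 0.05. MT-RNR2 alone took 15.3% to 19.2%. The nuclear long non-coding RNAs MALAT1 and NEAT1, chosen after their values were seen, set control library 1 apart. MALAT1 stood at 421601 there, against 102295 and 106343 in control libraries 2 and 3 and 76332 to 84705 with IKKe, and NEAT1 at 105611, against 18372 to 27644 in the other libraries. Their differences between the groups did not pass (adjusted p = 0.323 and 0.528). Structural small RNAs (18 tested, median 0.68) were higher as a list (camera adjusted p = 9.93e-06, adjusted p = 0.387 with an estimated correlation). Control library 2 lay at 0.75 above the control mean on this list, inside the IKKe range of 0.57 to 0.89, and control library 1 at -0.40. Of these RNAs, 3 rose adjusted over the list alone, 0 passed over all genes with limma or voom, and 10 were higher at an unadjusted p under 0.05; many are near-identical copies. The list turned to the lower side and did not pass after correction for GC content and length (adjusted p = 0.988). The 37 ribosomal protein genes did not pass (median 0.12, camera adjusted p = 0.405), with RPS2 at 0.15 ± 0.25 and RPL4 at -0.11 ± 0.21, and 0 of them passed with limma or voom or had an unadjusted p under 0.05. Of markers of other cell types, fibroblast (6 tested, camera adjusted p = 0.871), leukocyte (7 tested, 0.671) and endothelial lists (3 tested, 0.494) did not pass. None of their members passed with limma or voom, over all genes or adjusted over the list alone, and only 1, of the leukocyte list, was higher at an unadjusted p under 0.05. The fibroblast collagen gene COL3A1 stood at 1574 in control library 1 against 102 and 115 in control libraries 2 and 3. Its log2 fold change of -1.84 ± 0.93 did not pass (adjusted p = 0.334). The median of the fibroblast list was 0.03 and its mean -0.13. On this list of 6 tested genes control library 1 stood apart, at a median of 0.85 above the control mean. Control libraries 2 and 3 lay at -0.39 and -0.59, and the IKKe libraries between -0.12 and 0.16. The leukocyte genes LCP1 and CORO1A stood at 0.11 ± 0.23 and -0.0050 ± 0.18, and the endothelial gene EMCN at -0.32 ± 0.28.

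**Figure D3:**
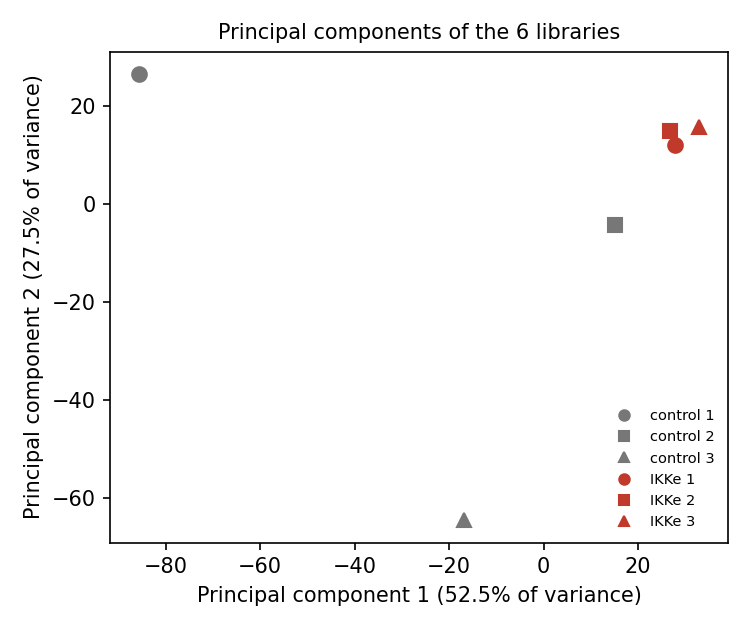
Positions of the 6 libraries on the first principal components of the log2 values of 16154 genes, with the share of variance on each axis (control grey, IKKe red; symbols mark the replicate). The IKKe libraries lie together near control library 2, while control library 1 stands apart on component 1 (52.5%) and control library 3 on component 2 (27.5%).

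The median SD of a gene on the log2 scale was 0.34 among control libraries and 0.08 among IKKe libraries. Pairs of control libraries differed by 15.8 to 16.3 times the sampling noise in the median chi-square per gene, and pairs of IKKe libraries by 1.32 to 1.38 times. Control library 2 lay closer to the IKKe libraries, at 5.23 to 5.51 times the noise, than to the other controls. At an unadjusted p under 0.05, 1622 genes were higher and 1188 lower, and in 28.7% of tested genes the groups did not overlap. By chance this share would be 10% if all 6 libraries were independent. The IKKe libraries lay so close to each other that this may not hold, and chance could then give a higher share. No excess over chance is concluded from it. Nothing in the labels says that the 3 libraries of a group came from separate cultures, and p-values then measure only the spread between these samples, which may be technical. The number of genes past the threshold rested on single libraries. The test uses a single spread per gene for both groups, while the median SD was 0.34 in controls against 0.08 with IKKe. At such values, leaving out an IKKe library raises the shared spread and leaving out a control library lowers it. How much of the change in the counts this gives was not tested. Without control library 1, 231 rose and 35 fell, without control library 2, 1504 and 832, without control library 3, 51 and 8, and with any 1 of the IKKe libraries left out 10 or 11 rose and 2 fell. Of the 30 named genes past the threshold, 12 passed with each of the 6 libraries left out in turn: IKBKE, IFNB1, IFNL1, IFNL2, IFNL3, CCL5, IGFBP6, HSPA6, RAET1L, PPP1R15A, CH507-338C24.1 and CTD-3074O7.11.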

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

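Under the alternatives, each named gene past the threshold kept its direction, but many changed their side of the threshold. The number of genes past the threshold and the calls of most lists also changed. The size of the change alone did not decide which genes held. S100A8 (log2 2.73) passed in 18 of 23 alternatives and PPP1R15A (log2 1.78) in all 23. Of 30 named genes past the threshold, 12 passed in all of up to 23 alternatives, namely IKBKE, IFNB1, IFNL1, IFNL2, IFNL3, CCL5, IGFBP6, HSPA6, RAET1L, PPP1R15A, CH507-338C24.1 and CTD-3074O7.11. The other 18 were each lost with some library left out, and 0 reversed. Fewer libraries alone do not explain this, as all 50 calls held without control library 1 or 2 (36 without 3). The cause was not tested. Of 16 lists past the threshold, 1 (interferons and IRF3 chemokines) passed in all 26 alternatives, 8 were lost only with an estimated correlation and 7 in 2 or more. With fry the estrogen receptor (0.0735), luminal (0.121), ATF4 (0.0566), immediate early (0.2) and structural small RNA (0.123) lists were lost, and after the spline the luminal (0.0603) and immediate early lists (0.061). The limma voom fits, the GC and length spline, the thinning, the fit without control libraries 1 and 3 and the combinations were chosen after the data were seen. Tests for whole reads were not run, since only 80.3% to 84.4% of nonzero values were whole. Without control libraries 1 and 3, the lone control was assumed to vary like the IKKe libraries. Calls and p-values from that fit therefore ignore the spread between controls. The least deep library held 16.7 M expected counts, so low genes carry more counting error there. No paired analysis was possible because the control titles carry numbers and the IKKe titles letters.

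Against 46 higher and 4 lower genes in the main test, more genes fell with no filter (9), equal totals (8), equal quantiles (10), no trend (7), a robust prior (10), voom (8) and thinning (8). Library weights gave 154 higher and 29 lower, protein-coding genes only 81 and 15, an adjusted p under 0.1 127 and 32, voom with quality weights 77 and 32, and the spline 138 and 23. Without control libraries 1 and 3 there were 1863 and 1534, with the spline and without control library 2 200 and 41, and with thinning and without control library 2 1118 and 686. With each library left out in turn, the counts ran from 10 (without IKKe library 1) to 1504 (without control library 2) higher and from 2 to 832 lower. With an estimated correlation 1 list passed, against 16. Across the alternatives 0 to 29 of 30 mitotic genes fell, 0 to 51 of 57 interferon-stimulated genes rose and 0 to 17 of 17 MHC class I genes rose, the most without control libraries 1 and 3. The alternatives with a looser threshold or fewer genes tested change the counts by construction. For the fit without control library 2 some causes were tested, as given under the other observations; for the rest the cause was not tested.

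Direction turned for 1 list past the threshold, structural small RNAs, which were lower after the spline (adjusted p = 0.988), and otherwise only for results that had not passed. TBK1 (log2 0.03) stood at -0.0019 with equal upper quartiles, -0.0396 with equal totals, -0.0393 with voom, -0.0288 with quality weights and -0.00058 after thinning. TBK1 ran from -0.15 to 0.15 with a library left out, and stood at 0.38 with the lone control that remains without control libraries 1 and 3. CHUK (-0.03) stood at 0.020 with library weights, 0.29 after the spline and 0.24 without control libraries 1 and 3, and ran from -0.16 to 0.051. IKBKB (0.09) ran from -0.033 to 0.20. IKBKG (0.33) stood at -0.043 after the spline. ESR1 (-0.19) stood at 0.0052 after the spline, ran from -0.56 to 0.024, and stood at -0.50 without control libraries 1 and 3. LPP, which had not passed, passed as lower in 12 of 23 alternatives.

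Among lists that did not pass, the adjusted p of fibroblast markers was 0.945 with equal quantiles, 0.878 with voom and 0.643 without control libraries 1 and 3, each with the direction turned, and ran from 0.281 to 0.941 with a library left out, turning without control library 1. Replication histones turned with library weights (0.765), the spline (0.00447) and without control libraries 1 and 3 (1.17e-09), and ran from 0.00792 to 0.941. Leukocyte markers turned after the spline (0.735) and without IKKe library 1, and ran from 0.308 to 0.866. Without control libraries 1 and 3, oxidative phosphorylation (0.207), ribosomal proteins (6.28e-10) and endothelial markers (0.652) turned as well. With a library left out, oxidative phosphorylation ran from 0.0126 to 0.477 (turned, without control library 1), ribosomal proteins from 0.00946 (turned, without control library 1) to 0.512, and DNA replication from 0.00114 to 0.563 (turned, without control library 2). Replication histones turned in 3 of the 6 fits with a library left out. Of lists that had not passed, mitochondrially encoded genes passed in 7 of 26 alternatives, the unfolded protein response and epithelial-mesenchymal transition in 6 each, p53 targets in 4, and heat shock and the kinase complexes in 1 each (fry). DNA replication and oxidative phosphorylation passed in 3 each, without a turn. Replication histones and ribosomal proteins also passed in 3 each, but in opposite directions. Without control library 2 both kept the direction of the main test (0.00792 and 0.0104), and in their other passes it was turned. For all of these the cause was not tested.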

Other observations

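The gene groups described first were chosen after the values were seen, as were the tests of IKKe material in control library 1 and of a library deposited 3 times, the spline and the thinning.

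Among interferon genes outside the lists, the 13 listed interferon alpha genes stayed below the filter, and 0 could be tested. The highest, IFNA7, had 12.1, 13.1 and 12.9 in the IKKe libraries against a control mean of 1.14 ± 1.04. None of 6 interferon receptor genes passed with limma or voom, and 1 was higher at an unadjusted p under 0.05, with a median log2 fold change of 0.02 that turned negative under 3 of 4 scalings. The interferon-stimulated genes IFIT1 and ISG15 had control means of 27779 and 13527, against 42377 and 26310 with IKKe, and did not pass. The class I genes HLA-A (1698 and 4607) and B2M (13511 and 25465) did not pass either.

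Of 7 tested NKG2D ligands only RAET1L rose, and the median was 0.58. Of 5 guanylate-binding proteins GBP1 rose, while GBP4 had means of 46.4 and 251 (adjusted p = 0.0532). The butyrophilin genes BTN3A1 (161 and 439), BTN3A2 (169.8 and 394) and BTN3A3 (129 and 358), which act in the recognition of cells by gamma-delta T cells, did not pass, and control library 1 alone stood at 290.05, 296 and 284. Of 5 tested butyrophilins 0 passed with limma or voom (1 rose with voom's quality weights), and 3 were higher at an unadjusted p under 0.05. CD274, which encodes PD-L1, had means of 131 and 296 (log2 1.29) and did not pass. Of 8 tested S100 genes S100A8 and S100P (506 to 1534, log2 1.61) rose, as did LCN2 (log2 2.31) and CFB (log2 1.57), genes of inflammation in epithelia.

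The IKKe libraries differed far less from each other than the control libraries did. A single library deposited 3 times would differ by no more than sampling noise or less, and the lowest chi-square of an IKKe pair was 1.32 times that noise. Lower depth of the controls does not account for the whole of it, since the control SD was still 3.63 times the IKKe SD after thinning, nor does GC content or length, with 3.65 times after the spline. Separate libraries of the same RNA or culture were not tested by these values and remain open, and no biological explanation was tested.

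Without control library 2, which lay nearest to the IKKe libraries, 2336 genes passed, against 50 with all libraries. After the spline on GC content and length the count without control library 2 was 241, the result predicted if such bias in control libraries 1 and 3 produced many of the calls. However, the correlation with GC content was -0.21 and -0.51 in these controls and 0.29 to 0.33 in the IKKe libraries. The spline would then also remove real group differences that follow GC content or length, so the fall cannot tell bias from these. With all libraries, 161 genes passed after the spline. Lower depth was excluded as the whole cause by 1804 genes after thinning, and loss of short RNAs because only 5.93% of the called genes had a longest transcript under 300 nt. Of the 10 splits of the 6 libraries into 3 and 3, the real split gave 50 genes and the highest other split 1, and 10 splits are too few for a share under 0.05.

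In control library 1, interferon-stimulated genes lay 0.43 on the log2 scale above the other controls, against 0.82 for the IKKe libraries, and 39 of 57 members were above both other controls. Material from IKKe transfection in this library would have raised IKBKE, which stood at 294, the lowest value of all libraries. Bias by GC content or length was excluded as the whole cause, as the difference was 0.40 after the spline. No biological explanation was tested.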
